A study of Homo sapiens with 16 samples.

How the data were processed

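The series holds 16 ChIP-seq samples of 2 established human cell lines: 12 immunoprecipitates of H3K4me3, H3K27me3 and H3K9me2, with 2 replicates per mark and line that the labels call biological, and 4 inputs. Per the labels' protocols, subconfluent cultures were used and libraries were sequenced as paired-end reads on an Illumina instrument. The labels' protocols also state that replicates were normalised and combined for further work, whereas the lists used here are per replicate. The submitters' processing notes name CASAVA 1.6, Bowtie2, MACS 1.4, bedtools and the build hg19, without their roles, settings or order. Whether and how the inputs served as controls is not given in the sources used here.

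Each deposited list has 5 columns: chromosome, start, end, a peak name and a score per peak. The score is the authors' own value. Its scale is not given in the sources used here. It was at least 50 in every deposited list, and many H3K4me3 peaks shared the value 3100, so ranks at the top of those lists are tied. The score was used only to rank or filter peaks within a list. Peaks on chromosomes 1 to 22 and X were kept; those on Y and on contigs not placed on a chromosome, 0.222% to 0.727% of a list, were left out of the comparisons. The largest end on chromosome 1 was 249240387. Coordinates are printed counting from 1. No list held overlapping peaks. The lists hold no read counts, so depth is unknown, and the precision rests on 2 replicates per group; a list with fewer peaks can reflect fewer reads or a weaker enrichment, which the lists cannot separate. Intervals on shares of regions are exact Clopper-Pearson intervals at 95% and cover counting error only. Fisher's exact tests likewise take regions as independent, and their p-values do not measure the spread between replicates.

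Computations used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6, R 4.3.3 with limma 3.58.1, and matplotlib 3.10.9 for the figures. Samples were grouped by mark and line from the labels. The main tests, their alternatives and the rule for named regions were fixed before the data were examined. Peak numbers, covered bases and widths were compared with two-sided exact permutation tests. Overlap of libraries was measured as the Jaccard index of covered bases for the 6 pairs of libraries per mark.

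For regions, the peaks of the 4 libraries of a mark were merged where they overlapped by at least 1 bp. A region was assigned to a line when both of its replicates and neither of the other line's had a peak there, and to the shared class when all 4 did. The same count for the splits that mix the lines gave the background. Region counts carry no p-value. The 5 regions named per mark and class had the highest value of the lower of their within-list score percentiles, with ties in chromosome order, and the text gives a part of them. Of the bins, the 3 with the smallest limma p per mark and direction were named.

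For bins, covered bases in 1 Mb windows were expressed as covered bp per Mb of a library's total coverage (bp/Mb), and log2 of this value plus a pseudocount of 10 bp/Mb was tested with limma (trend and empirical Bayes) on bins covered in at least 2 of the 4 libraries of a mark. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Log2 ratios of bins are on this scale, which understates the change of low bins, and no fold is given against a line listed at 0. The alternatives were pseudocounts of 1 and 50 bp/Mb, all bins with any coverage, unscaled coverage in kb with a pseudocount of 1 kb, bins of 250 kb, the replicate number as a block, peaks with a score of at least 100, equal numbers of top-scoring peaks, and each library left out in turn.

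Overlaps of marks within a line were tested by permutation, with 1000 circular shifts of a list along the joined chromosomes, two-sided, with 0.002 as the smallest p. Added after seeing the data were shifts within each chromosome, local moves of 50 to 500 kb, scaling of bins within chromosomes, the pair H3K9me2 and H3K27me3, the comparison of bins between marks, the comparison of H3K27me3 on classes of H3K4me3 regions (Fisher's exact test with Benjamini-Hochberg adjustment over 8 tests, Fisher's exact tests of the split between the lines against that in shared regions over 4 tests, and 10000 one-sided shifts of the class labels), and the chromosome shares with their correlations (100000 permutations).

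The bin test, the region classes and the shifts of lists were tested on simulated data, and the other steps were not. In the bin test 200 bins were changed. For H3K4me3 (2382 bins) all were recovered at 2-, 4- and 32-fold. For H3K27me3 (2100 bins) 4.29%, 32.9% and 85% were recovered at these sizes, and for H3K9me2 (2334 bins) 2.86%, 21.4% and 71.7%. Of the calls made, 5.66%, 4.94% and 4.76% were false for H3K4me3, H3K27me3 and H3K9me2. In this simulation the bin test missed most changes of 4-fold or less in the repressive marks. In the data far more bins were called, 1118 for H3K27me3 and 1251 for H3K9me2, so these recovery shares need not hold there. The simulated spread was set to each bin's empirical Bayes value and the 32-fold class was added after a first run had recovered few changes. Simulated values had no floor. In the data, 531 H3K27me3 and 881 H3K9me2 bins called higher in MCF-10A were listed at 0 in both MDA-MB-231 libraries. The recovery and false shares do not cover such bins. All 200 regions planted per line were found. In 100 unrelated pairs of lists, 1 had a shift p below 0.05, after an artefact of the simulated positions had been corrected.

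Of the planned results, 4 were not run because no gene annotation of hg19 was used here: promoters by line, gene lists by line, promoters with both H3K4me3 and H3K27me3, and the distribution over gene parts. The gene lists fixed for them were therefore not tested.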

Results

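Genome-wide maps of 3 histone H3 modifications were compared between MCF-10A, a non-tumorigenic human breast epithelial cell line, and MDA-MB-231, a breast cancer cell line derived from a metastatic site. H3K4me3 is a mark of active and poised promoters, H3K27me3 is deposited by Polycomb repressive complexes, and H3K9me2 is a mark of silenced chromatin. Chromatin immunoprecipitation and sequencing (ChIP-seq) had been done in 2 biological replicates per mark and line, which gave 12 peak lists, and the series title places the work in a study of DNA attached to the nuclear matrix. The 4 input libraries came without a peak list of their own and were not analysed here. The lists give no read counts, so the sequencing depth behind each peak is unknown. All positions are given on hg19, for chromosomes 1 to 22 and X, and no gene is named because no annotation of that build was used here.

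H3K4me3 was called at a similar number of sites in both lines. The lists held 15568 and 16776 peaks in MCF-10A and 16578 and 16193 peaks in MDA-MB-231, covering 20.98 ± 1.397 Mb and 21.6 ± 0.04998 Mb (mean ± SD, n = 2). H3K9me2 peaks were fewer in MDA-MB-231, with 6147 and 5045 peaks against 10656 and 8885 in MCF-10A, and wider, with a median width of 2035 ± 232 bp against 1591.5 ± 20.5 bp (SD, n = 2). H3K27me3 gave 28896 and 28955 peaks in MCF-10A, but 8470 and 30496 peaks in MDA-MB-231. MDA-MB-231 replicate 1 of H3K27me3 covered 6.54 Mb against 19.6 Mb in replicate 2, and 8.43% of its peaks had a score of at least 100, against 23.3% to 26.1% in the other 3 H3K27me3 lists. The log2 ratio of mean peak number, MDA-MB-231 over MCF-10A, was −0.57 for H3K27me3. Without MDA-MB-231 replicate 1 it was 0.08, and without MDA-MB-231 replicate 2 it was −1.77. For H3K9me2 the log2 ratio was −0.80. Two-sided exact permutation tests of peak number gave p = 1, 1 and 0.333 for H3K4me3, H3K27me3 and H3K9me2, and 0.333 is the smallest p that 2 against 2 libraries allow.

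Replicates of H3K4me3 overlapped closely, and those of the repressive marks much less. The Jaccard index of covered bases (shared bases over all covered bases) was 0.806 between the MCF-10A replicates and 0.8001 between the MDA-MB-231 replicates of H3K4me3, and 0.680 to 0.696 across lines. For H3K9me2 it was 0.435 and 0.355 within the lines and 0.120 to 0.126 across them. For H3K27me3 it was 0.259 within MCF-10A and 0.0957 within MDA-MB-231, and the pairs across lines ranged from 0.0461 to 0.0965. By this index the MDA-MB-231 replicates of H3K27me3 did not exceed the closest pair across lines, but lists of unlike length limit the index. The pairs of MCF-10A replicates 1 and 2 with the short MDA-MB-231 replicate 1 had only 0.0485 and 0.0461. Of the peaks of MDA-MB-231 replicate 1, 48.0% overlapped MDA-MB-231 replicate 2, against 27.2% and 25.7% for MCF-10A replicates 1 and 2.

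**Figure D1:**
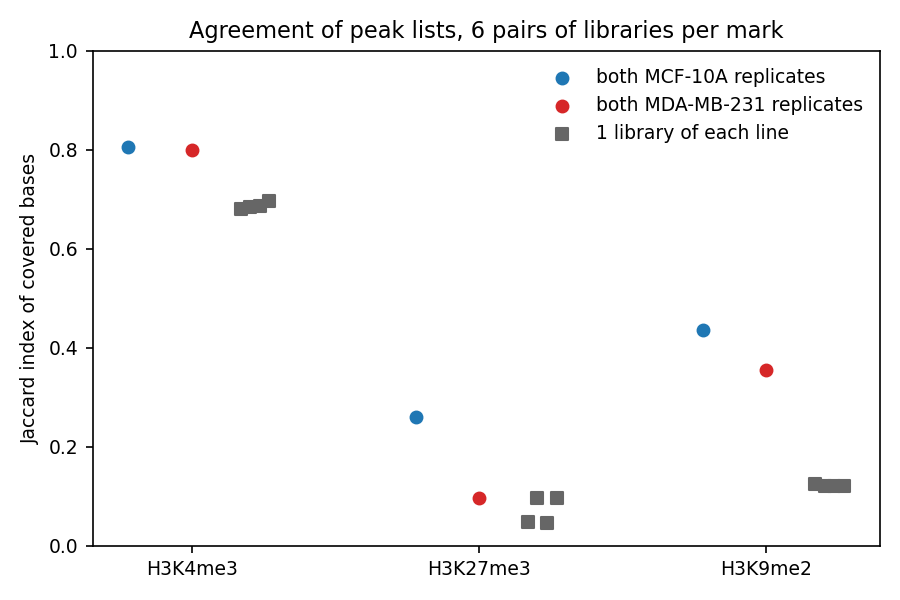
Jaccard index of covered bases (y axis, from 0 to 1) for the 6 pairs of libraries of each mark (x axis); circles are the replicate pairs of a line and squares are pairs with 1 library of each line. Both H3K4me3 and both H3K9me2 replicate pairs lie above every pair across lines, whereas the MDA-MB-231 pair of H3K27me3, at 0.0957, does not.

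Most H3K4me3 regions were common to both lines. Of 18048 merged regions, 12367 (68.5%) were present in all 4 libraries, 1067 only in both MCF-10A libraries and 1131 only in both MDA-MB-231 libraries. Among the top-ranked regions found only in MCF-10A were chromosome 1 from 27285872 to 27287569, chromosome 4 from 123747498 to 123749787, and chromosome 5 from 1882302 to 1887890 and from 2748280 to 2751905. The regions on chromosome 1 and at 2748280 on chromosome 5 overlapped H3K27me3 peaks in both MDA-MB-231 replicates. Top-ranked regions found only in MDA-MB-231 included chromosome 4 from 57974935 to 57977163, chromosome 6 from 166073752 to 166077311, chromosome 17 from 39682792 to 39684957 and chromosome 19 from 41724536 to 41728342. Splits that mixed the lines gave 143 and 149, and 9 and 90 such regions, so the line split exceeded the spread between replicates. Without MCF-10A replicate 1 the MCF-10A count was 2121, and without MDA-MB-231 replicate 1 or 2 the MDA-MB-231 count was 1791 or 1950. Counting either replicate gave 2192 and 2274.

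H3K27me3 regions varied between libraries and lines. Of 66286 merged regions, 7389 were found only in both MCF-10A libraries, 1982 only in both MDA-MB-231 libraries and 1174 (1.77%) in all 4, while 72.5% were present in 1 library only. Of the regions in both MCF-10A libraries 10.2% were also in both MDA-MB-231 libraries, and of those in both MDA-MB-231 libraries 29.9% were also in both MCF-10A libraries. The highest-ranked region found only in MCF-10A lay on chromosome 18 from 76773927 to 76777395, followed by chromosome 7 from 43150819 to 43154334 and chromosome 8 from 145560591 to 145564380. The 3 highest-ranked regions found only in MDA-MB-231 lay together on chromosome 19, from 8851364 to 8856555, from 8864161 to 8878839 and from 8879671 to 8884513, and overlapped H3K9me2 of MDA-MB-231, the first in both replicates and the others in replicate 2 only. The next, on chromosome 14 from 104582522 to 104585122 and on chromosome 1 from 201366874 to 201369215, overlapped H3K4me3 peaks in both MCF-10A replicates. The mixed splits gave 273 and 1758, and 1707 and 265 regions. The 273 and 265 came from pairs that, like the MDA-MB-231 pair, held the short MDA-MB-231 replicate 1. The 1758 and 1707 came from pairs of 2 long lists. The MDA-MB-231 count of 1982 was far above the 273 and 265 and close to the 1758 and 1707. The MCF-10A count, from 2 long lists, was far above all of them. Without MCF-10A replicate 1 or 2 the MCF-10A count was 21695 or 21552, and without MDA-MB-231 replicate 1 or 2 the MDA-MB-231 count was 21119 or 5488, and the number in all 4 rose to 3706 without MDA-MB-231 replicate 1. A score of at least 100 left 2817, 203 and 131 regions, equal list lengths gave 2815 MCF-10A regions and 470 in all libraries, coverage of at least 50% of the region gave 193 in all libraries, and counting either replicate gave 33397, 24028 and 8861.

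H3K9me2 regions varied in a similar way. Of 18327 merged regions, 4294 were found only in both MCF-10A libraries, 1672 only in both MDA-MB-231 libraries and 971 (5.30%) in all 4, and 52.4% were present in 1 library only. Of the regions in both MCF-10A libraries 15.95% were also in both MDA-MB-231 libraries, and of those in both MDA-MB-231 libraries 31.7% were also in both MCF-10A libraries. Top-ranked MCF-10A regions lay on chromosome 16 from 89019982 to 89023385 and on chromosome 19 from 380572 to 383477, both with H3K27me3 in both MCF-10A replicates, and on chromosome 14 from 105325071 to 105329291. The highest-ranked MDA-MB-231 region was on chromosome 19 from 8851342 to 8856406, followed by chromosome 6 from 40522698 to 40532344, which carried H3K27me3 in all 4 libraries of that mark. The mixed splits gave 230 and 68, and 146 and 108 regions. Without MCF-10A replicate 1 or 2 the MCF-10A count was 6721 or 8150, and without MDA-MB-231 replicate 1 or 2 the MDA-MB-231 count was 3035 or 3895. A score of at least 100 left 985, 223 and 131 regions, equal list lengths gave 2043 MCF-10A regions, and counting either replicate gave 10462, 5100 and 2765.

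A block of 46.3 kb on chromosome 19, from 8851342 to 8897616, held the 3 highest-ranked H3K27me3 regions and the highest-ranked H3K9me2 region found only in MDA-MB-231. H3K27me3 peaks covered 62.5% and 93.2% of it in MDA-MB-231 replicates 1 and 2, and H3K9me2 peaks covered 25.7% and 93.9%. In MCF-10A the cover was 2.27% and 0% for H3K27me3 and 0% and 4.58% for H3K9me2. No H3K4me3 peak lay in the block in any of the 4 libraries of that mark. The first peak of the block started between 8851342 and 8851425 in all 4 MDA-MB-231 lists of the repressive marks, and the last one ended between 8897495 and 8897616. The block itself was chosen after its values were seen, and no test was made of it. Its copy number was not measured, because the inputs were not analysed here. A local gain of DNA in MDA-MB-231 and a difference in the marks themselves cannot be told apart.

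**Figure D2:**
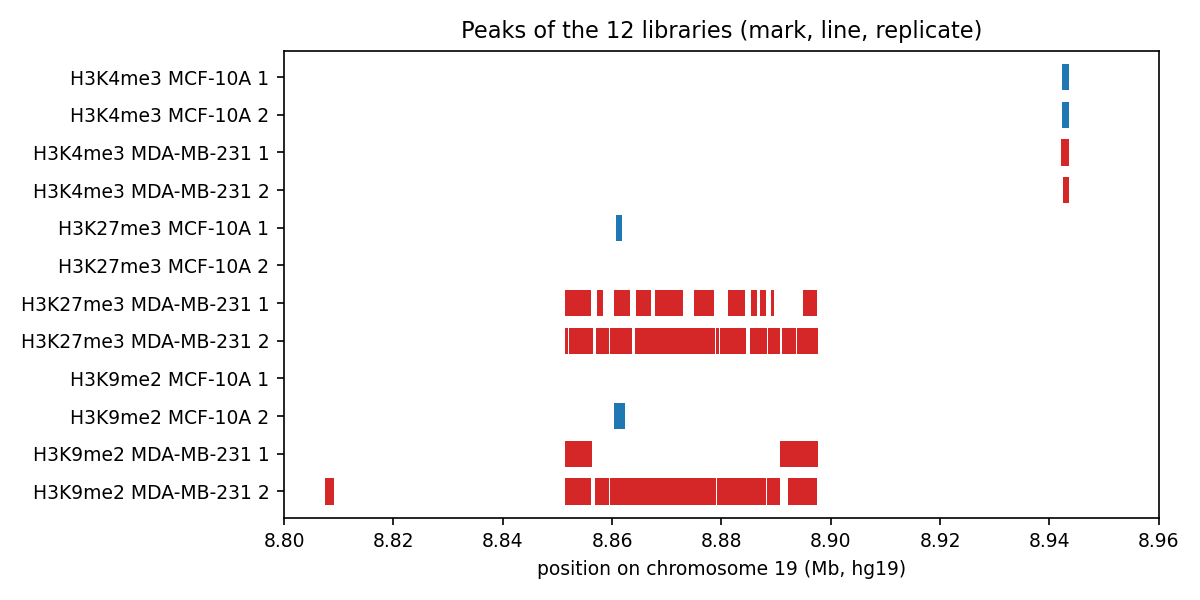
Peaks (bars) of the 12 libraries on chromosome 19 between 8.8 and 8.96 Mb (x axis, hg19 position in Mb), with 1 library per line of the plot (mark, cell line, replicate), MCF-10A in blue and MDA-MB-231 in red. The H3K27me3 and H3K9me2 peaks of MDA-MB-231 reach from about 8851342 to 8897616 in all 4 lists, covering 25.7% to 93.9% of that block, and MCF-10A has 1 narrow peak in 1 list of each of these marks there.

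Coverage was next compared in bins of 1 Mb, as covered bp per Mb of a library's total coverage (bp/Mb), with limma and Benjamini-Hochberg adjustment. H3K4me3 coverage was higher in MDA-MB-231 in 427 of 2382 bins and higher in MCF-10A in 407, with a median absolute log2 ratio of 0.48 among them. The bin with the smallest p was on chromosome X from 114000001 to 115000000, at 1269 and 1294 bp/Mb in MCF-10A against 78.5 and 79.3 bp/Mb in MDA-MB-231 (log2 ratio −3.86, SE 0.0624, limma adjusted p = 8.67e-06). The bin on chromosome 7 from 27000001 to 28000000 had a log2 ratio of −2.28 (SE 0.0543, limma adjusted p = 3.78e-05), and that on chromosome 5 from 2000001 to 3000000 held 302 and 321 bp/Mb in MCF-10A and was listed at 0 in MDA-MB-231. In the other direction, bins on chromosome 20 from 22000001 to 23000000, chromosome 16 from 32000001 to 33000000 and chromosome 5 from 83000001 to 84000000 held 190 to 237 bp/Mb in the MDA-MB-231 libraries and were listed at 0 in MCF-10A (limma adjusted p = 0.000127 each). The counts rested on the full set of libraries: without MCF-10A replicate 1, MCF-10A replicate 2, MDA-MB-231 replicate 1 or MDA-MB-231 replicate 2 they were 44 and 67, 62 and 73, 62 and 111, or 68 and 112. Unscaled coverage gave 259 bins higher in MCF-10A, and bins of 250 kb gave 706 and 626.

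H3K27me3 coverage was higher in MCF-10A in 802 of 2100 bins and higher in MDA-MB-231 in 316, so 28.3% of the called bins were higher in MDA-MB-231. Unscaled coverage in kb gave 834 and 57, or 6.40%. In 531 of the 802 bins both MDA-MB-231 libraries were listed at 0. The bin on chromosome 8 from 11000001 to 12000000 held 6103 and 6016 bp/Mb in MCF-10A against 745 and 837 bp/Mb in MDA-MB-231 (log2 ratio −2.92, SE 0.100, limma adjusted p = 0.00286). Scaled within chromosome 8 its log2 ratio was −0.85 (limma adjusted p = 0.0293), and with a score of at least 100 it was −6.76 but did not pass (limma adjusted p = 0.14). Bins on chromosome 8 from 72000001 to 73000000 and chromosome 15 from 70000001 to 71000000 held 1694 to 1945 bp/Mb in MCF-10A and were listed at 0 in MDA-MB-231. The bin on chromosome 6 from 41000001 to 42000000 was higher in MDA-MB-231, at 8119 and 7621 bp/Mb against 1624 and 1442 bp/Mb (log2 ratio 2.35, SE 0.0928, limma adjusted p = 0.00286), and did not pass with unscaled coverage (log2 ratio 1.42, limma adjusted p = 0.212). The median log2 ratio over all bins tested was −1.21, −0.98 when coverage was scaled within each chromosome and −1.10 unscaled, and the values above are not corrected for this shift. Without MCF-10A replicate 1 or 2 the bins higher in MDA-MB-231 numbered 106 or 104. Bins of 250 kb gave 634 and 1782, a score of at least 100 gave 75 and 523, and equal list lengths gave 459 bins higher in MCF-10A.

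H3K9me2 coverage was higher in MCF-10A in 984 of 2334 bins and higher in MDA-MB-231 in 267, and 881 of the 984 were listed at 0 in both MDA-MB-231 libraries. The bin on chromosome 20 from 57000001 to 58000000 held 11608 and 10797 bp/Mb in MDA-MB-231 against 1096 and 1062 bp/Mb in MCF-10A (log2 ratio 3.36, SE 0.0671, limma adjusted p = 0.000674). With coverage scaled within chromosome 20 its log2 ratio was 0.56. The same bin of chromosome 6 that was higher for H3K27me3, from 41000001 to 42000000, had an H3K9me2 log2 ratio of 4.76 (SE 0.120, limma adjusted p = 0.000674), and 3.82 scaled within the chromosome. Among the bins higher in MCF-10A were chromosome 6 from 136000001 to 137000000, chromosome 12 from 78000001 to 79000000 and chromosome 2 from 50000001 to 51000000, at 69.5 to 76.0 bp/Mb and listed at 0 in MDA-MB-231. Each held only 1099 to 1448 covered bp per MCF-10A library, less than 1 peak of median width (1606 and 1577 bp). These calls therefore rest on very little coverage, set against a floor without spread. With a score of at least 100 or equal list lengths these 3 bins were covered in too few libraries to be tested. The median log2 ratio of all bins was −2.24, −1.99 scaled within chromosomes and −1.42 unscaled. Without MCF-10A replicate 2 the bins higher in MDA-MB-231 numbered 161, and without MCF-10A replicate 1 they numbered 177. Bins of 250 kb gave 601 and 2359, and a score of at least 100 gave 101 and 556.

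The repressive marks changed in the same bins more often than independent lists would. Of 1887 bins tested for both, 150 were higher in MDA-MB-231 for both H3K27me3 and H3K9me2 against 41.1 for independent lists, 427 were higher in MCF-10A for both against 252, and 27 went in opposite directions against 204. The log2 ratios of both marks correlated across bins at r = 0.62, although neighbouring bins are not independent. With scaling within chromosomes the counts were 110, 352 and 38, and r was 0.52. H3K4me3 and H3K27me3 changed in opposite directions in 174 of 1928 bins against 180 for independent lists, and their log2 ratios had r = −0.02. With scaling within chromosomes 182 bins went in opposite directions against 146, with r = −0.07. H3K4me3 and H3K9me2 were both higher in MDA-MB-231 in 65 of 2057 bins against 43.8, both higher in MCF-10A in 188 against 139, and opposite in 141 against 183 (r = 0.07), and with scaling within chromosomes in 43 against 36.9, 148 against 124 and 167 against 165. These comparisons between marks were not tested.

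H3K4me3 regions found only in MDA-MB-231 carried H3K27me3 in MCF-10A far more often than regions shared by the lines. Of the 1131 regions, 206 (18.2%, exact 95% interval 16.01 to 20.6%) overlapped H3K27me3 of both MCF-10A replicates, against 236 (1.91%) of the 12367 regions in all 4 libraries. In MDA-MB-231 itself 17 (1.503%) overlapped H3K27me3 of both replicates, 1.95% that of replicate 1 and 4.16% that of replicate 2, and in MCF-10A these single-replicate shares were 24.0% and 21.3%. Examples with H3K27me3 in both MCF-10A replicates and in neither MDA-MB-231 replicate, 176 in all, lay on chromosome 16 from 65153995 to 65158046, chromosome 7 from 82071700 to 82074162 and chromosome 7 from 79081293 to 79083610. The odds ratio against shared regions was 11.4 (two-sided Fisher's exact test, p = 9.6e-107, adjusted p = 7.68e-106 over 8 tests), and a shift of the region classes along the genome gave p = 0.0001, the smallest it can give. Counting only H3K27me3 present in both replicates of a line, 197 of these regions carried the mark in MCF-10A alone and 8 in MDA-MB-231 alone. In the shared regions, where the longer MCF-10A list also counts, the numbers were 215 and 35, and the splits differed (odds ratio 4.01, Fisher's exact test, p = 0.000182, adjusted p = 0.000243 over 4 tests). With a score of at least 100 the odds ratio was 21.5. For MDA-MB-231 H3K27me3 on the same regions the odds ratio was 3.35 (Fisher's exact test, adjusted p = 0.000171), and with that score 1.85 (Fisher's exact p = 0.45). The 8 tests also held H3K9me2. On these regions its odds ratio was 0.423 for MCF-10A (Fisher's exact test, adjusted p = 0.0159) and 1.37 for MDA-MB-231 (Fisher's exact test, adjusted p = 0.491).

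H3K4me3 regions found only in MCF-10A were compared in the same way with H3K27me3 of MDA-MB-231. Of the 1067 H3K4me3 regions found only in MCF-10A, 35 (3.28%, exact 95% interval 2.30 to 4.53%) overlapped H3K27me3 of both MDA-MB-231 replicates, against 56 (0.453%) of the shared regions, an odds ratio of 7.46 (Fisher's exact test, p = 4.41e-16, adjusted p = 1.76e-15). The share was 4.87% with H3K27me3 replicate 1 and 10.5% with replicate 2 of MDA-MB-231. H3K9me2 of MDA-MB-231 lay on 9 of the 1067 regions (odds ratio 4.37, Fisher's exact test, adjusted p = 0.00131). That of MCF-10A lay on 11 of them (odds ratio 0.618, Fisher's exact test, adjusted p = 0.147). The 26 regions with H3K27me3 in MDA-MB-231 and in no MCF-10A library included chromosome 6 from 39194723 to 39197617 and chromosome 2 from 14772130 to 14775788. The same 1067 regions carried MCF-10A H3K27me3 more often than MDA-MB-231 H3K27me3, with 66 (6.19%) overlapping it in both MCF-10A replicates. Against shared regions this was an odds ratio of 3.39 (Fisher's exact test, adjusted p = 5.09e-14). H3K27me3 lay on 62 of the regions in both replicates of MCF-10A alone and on 31 in MDA-MB-231 alone. The consensus H3K27me3 list of MCF-10A was longer, with 11536 regions against 3873, and against the 215 and 35 of the shared regions the split was shifted towards MDA-MB-231 (odds ratio 0.326, Fisher's exact test, p = 0.000105, adjusted p = 0.000211). The shares of the opposite directions were not tested against each other. Without MCF-10A H3K4me3 replicate 1 the odds ratio of 7.46 was 4.89, and with a score of at least 100 it was 19.3. The comparison of region classes was chosen after the overlap of the lists had been seen. Its intervals and Fisher p-values cover counting error only, with regions taken as independent, and not the spread between replicates.

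**Figure D3:**
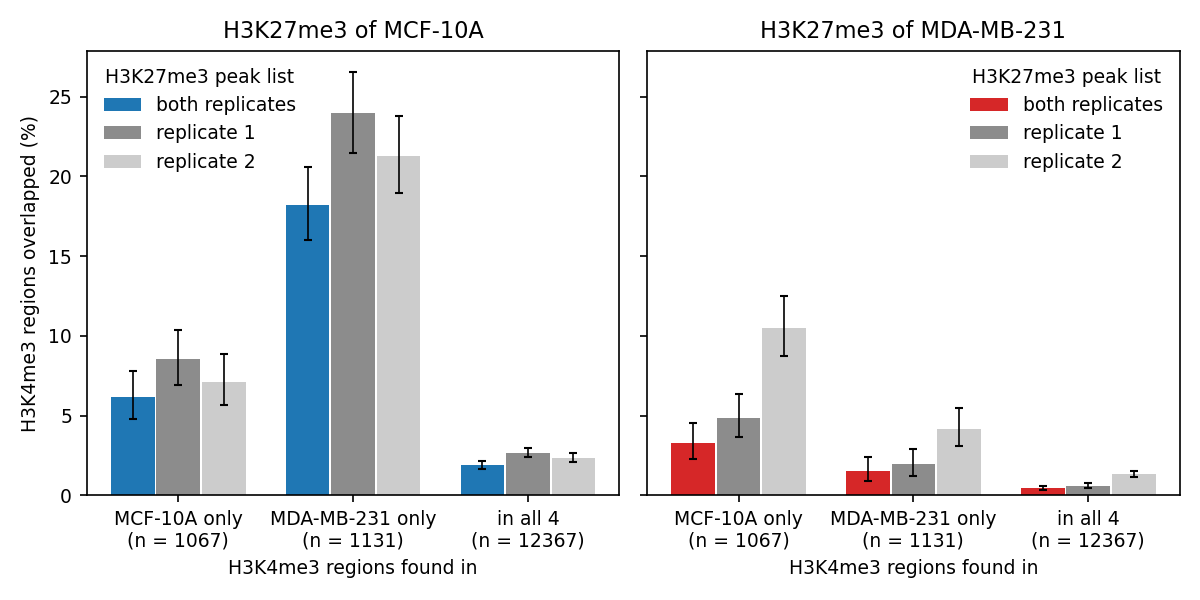
Percent of H3K4me3 regions overlapped by H3K27me3 peaks (y axis) for regions found only in MCF-10A, only in MDA-MB-231 or in all 4 libraries (x axis), with H3K27me3 of MCF-10A on the left and of MDA-MB-231 on the right; bars give the peaks present in both replicates or in each single replicate, and error bars are exact 95% binomial intervals. MCF-10A H3K27me3 lay on 18.2% of the regions found only in MDA-MB-231 and on 1.91% of the shared regions.

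Within a line, overlaps of the marks were set against lists moved along the genome. In MCF-10A 2.12% of 14181 H3K4me3 regions overlapped H3K27me3, 2.13 times the value of shifted lists (two-sided permutation p from shifts = 0.002, the smallest it can give), and 1.54% overlapped H3K9me2, a fold of 2.08 (permutation p = 0.002). In MDA-MB-231 0.502% of 14348 H3K4me3 regions overlapped H3K27me3, a fold of 1.44 (permutation p = 0.05), and 0.174% overlapped H3K9me2, a fold of 0.385 (p = 0.002). H3K9me2 and H3K27me3 coincided in both lines: 7.54% of 6103 H3K9me2 regions in MCF-10A and 14.3% of 3074 in MDA-MB-231 overlapped H3K27me3, folds of 6.48 and 30.4 (permutation p = 0.002 each). Across lines 13.96% of the MDA-MB-231 H3K9me2 regions overlapped H3K27me3 of MCF-10A and 2.08% of the MCF-10A regions H3K27me3 of MDA-MB-231, folds of 10.2 and 5.22 (permutation p = 0.002 each). These folds fell when each region was moved only 50 to 500 kb: to 1.06 (permutation p = 0.308) and 1.37 (p = 0.002) for H3K4me3 with H3K27me3 and with H3K9me2 in MCF-10A, to 0.654 (p = 0.002) and 0.219 (p = 0.002) in MDA-MB-231, and to 2.31 and 3.52 (p = 0.002 each) for H3K9me2 with H3K27me3. Against local moves the H3K4me3 overlap with H3K27me3 of single replicates had folds of 0.688 to 1.07 in MCF-10A. The H3K27me3 overlap in MDA-MB-231 changed direction with the kind of shift, and the fold of 1.44 was 0.874 without replicate 1 and 1.05 without replicate 2. Without replicate 1 or 2 the fold of 30.4 was 17.2 or 20.1; shifts within each chromosome gave 14.8 in its place, and a score of at least 100 gave 86.3. With that score the H3K4me3 overlap with H3K9me2 in MDA-MB-231 had a fold of 0.669 (permutation p = 0.394), and the H3K9me2 overlap with H3K27me3 in MCF-10A a fold of 11.2.

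The share of each chromosome in the covered bases differed between the lines, most for the repressive marks. Chromosome 20 held 4.42 ± 0.00181% of H3K27me3 coverage in MCF-10A and 12.4 ± 0.676% in MDA-MB-231, and 1.77 ± 0.0993% and 12.5 ± 0.659% of H3K9me2 coverage (SD, n = 2). Chromosome 16 went the other way, from 6.22 ± 0.0677% to 1.21 ± 0.119% for H3K27me3 and from 6.47 ± 0.190% to 0.422 ± 0.143% for H3K9me2, as did chromosome 8, from 10.3 ± 0.282% to 2.43 ± 0.281% and from 12.3 ± 0.561% to 3.43 ± 0.243%. H3K4me3 shares moved far less, from 2.45% to 2.71% on chromosome 20 and from 4.75% to 3.997% on chromosome 16. The SD of the log2 ratio over 23 chromosomes was 0.0928 for H3K4me3, 1.01 for H3K27me3 and 1.56 for H3K9me2. The replicates of the lines did not overlap on 20, 22 and 22 of the 23 chromosomes, where chance gives 33.3%. With a score of at least 100 the H3K27me3 log2 ratio of chromosome 16 was −4.02 in place of −2.36, and that of chromosome 13 was −3.79 in place of −1.76.

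The log2 ratios of the chromosome shares correlated between marks across the 23 chromosomes. For H3K27me3 and H3K9me2 Pearson's r was 0.936 (permutation p = 1e-05) and Spearman's rho 0.937 (permutation p = 1e-05), with the same sign on 21 chromosomes. For H3K4me3 and H3K27me3 r was 0.812 (permutation p = 1e-05) and rho 0.817 (permutation p = 2e-05), and for H3K4me3 and H3K9me2 r was 0.855 and rho 0.882 (permutation p = 1e-05 each), each with the same sign on 16 chromosomes. Leaving out the 2 chromosomes farthest from the median gave r of 0.934, 0.807 and 0.801. Over these 3 relations the adjusted p of r was 1e-05 throughout, and 1e-05 is the smallest p of 100000 permutations. The adjusted p of rho was 1.5e-05 for both relations with H3K9me2 and 2e-05 for the third. The chromosome comparison was chosen after the shares were seen, and whether the same input served as control for several marks is not given in the sources used here.

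**Figure D4:**
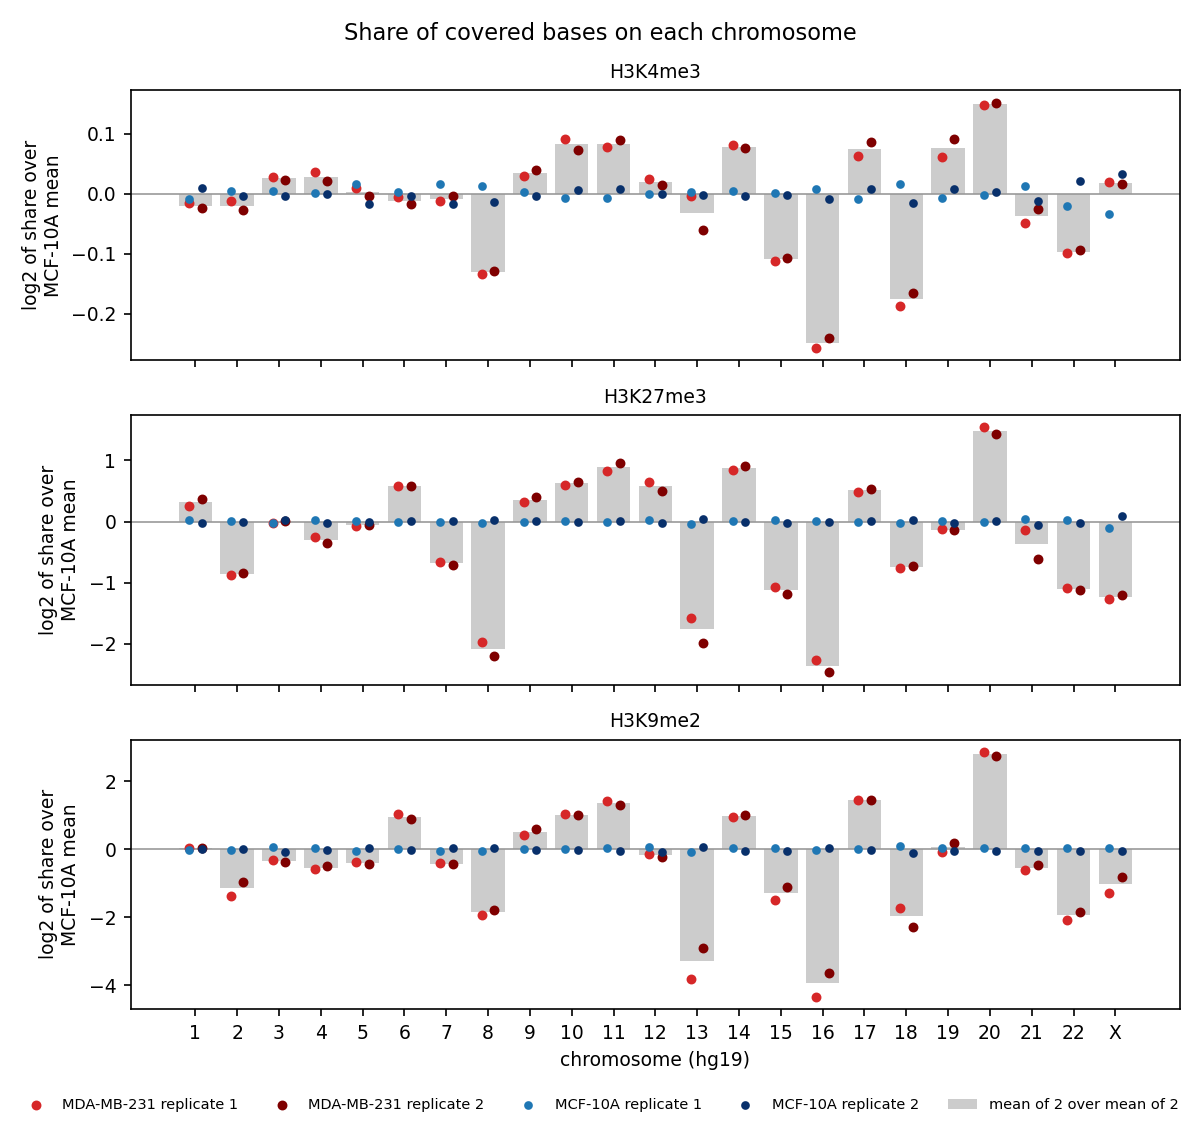
Log2 of the share of covered bases on each chromosome (x axis, hg19) over the mean share of MCF-10A (y axis), for H3K4me3, H3K27me3 and H3K9me2 from top to bottom, each with its own scale; points are libraries and grey bars the mean of MDA-MB-231 over the mean of MCF-10A. Chromosome 20 has the highest ratio and chromosome 16 the lowest for all 3 marks, and the scale is much smaller for H3K4me3.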

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

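Chosen only after their results were seen were the local moves, the comparison without MDA-MB-231 replicate 1 of H3K27me3 on chromosome shares, and the share of MCF-10A H3K27me3 on regions found only in MCF-10A. The 3 patterns weighed here were themselves noticed in the data.

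H3K4me3 regions with H3K9me2 lay on opposite sides of 1 in the lines against local moves, at a fold of 1.37 in MCF-10A and 0.219 in MDA-MB-231. Every combination of single replicates gave the same sides, with 1.19 to 1.26 in MCF-10A and 0.164 to 0.216 in MDA-MB-231. H3K4me3 of MDA-MB-231 with H3K9me2 of MCF-10A had a fold of 1.28 over local moves (permutation p = 0.002). H3K4me3 of MCF-10A with H3K9me2 of MDA-MB-231 had a fold of 0.290 (permutation p = 0.002). The side of 1 went with the H3K9me2 list used. Most H3K4me3 regions were common to the lines: 89.6% of those in both MCF-10A libraries and 88.6% of those in both MDA-MB-231 libraries were in all 4. Exchanging the H3K4me3 lists therefore changed few regions and cannot tell what line-specific H3K4me3 contributes. The folds of 0.219 and 0.290 rested on 25 and 32 overlapping regions. The difference between the lines was not tested.

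Peaks on contigs not placed on a chromosome were left out of the comparisons and numbered up to 47 in a library for H3K4me3, 122 for H3K27me3 and 43 for H3K9me2. No input peak list was there to set beside them.

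The chromosome shares of H3K27me3 and H3K9me2 differed strongly between the lines, and those of H3K4me3 slightly in a correlated way, with the same sign as either repressive mark on 16 of 23 chromosomes. The short H3K27me3 list of MDA-MB-231 replicate 1 is argued against as the cause, since without that library the SD of the log2 ratio over chromosomes was 1.05 against 1.01 with it. Copy number of the chromosomes may contribute, but the test made for it cannot decide. At H3K4me3 regions present in all 4 libraries, the median log2 width ratio per chromosome correlated with the H3K27me3 share at r = 0.804 (permutation p = 1e-05). These regions hold most H3K4me3 coverage, and the similar correlation of H3K4me3 shares had been seen when this test was chosen. Not every chromosome followed: chromosome X had a log2 width ratio of 0.137, but log2 share ratios of −1.23 for H3K27me3 and −1.03 for H3K9me2. Copy number was not measured, because the inputs were not analysed here, and it does not by itself say why the SD was 1.01 and 1.56 for the repressive marks and 0.0928 for H3K4me3. A difference of the lines in the marks themselves, and a calling threshold that acts more on weak marks, stay open as untested.

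H3K4me3 regions found only in MDA-MB-231 carried H3K27me3 of MCF-10A at an odds ratio of 11.4 against shared regions. Differences in peak density between chromosomes are argued against as the whole cause by a Mantel-Haenszel odds ratio over chromosomes of 11.7 (95% interval 9.53 to 14.3), and region width by one over 10 width classes of 7.63 (5.92 to 9.82). That any line-specific region carries MCF-10A H3K27me3 alike is argued against by the 6.19% of regions found only in MCF-10A, against 18.2%. That 6.19% still exceeded the 1.91% of shared regions (odds ratio 3.39, Fisher's exact test, adjusted p = 5.09e-14). For MDA-MB-231 H3K27me3 on regions found only in MDA-MB-231 the odds ratio was 3.35. An excess common to line-specific regions can therefore be part of the 11.4. A candidate explanation is that some regions with H3K27me3 in MCF-10A carry H3K4me3 in its place in MDA-MB-231, a hypothesis found and tested on the same lists. Seen from H3K27me3 regions found only in MCF-10A it was not borne out. Their H3K4me3 split, 59 in MCF-10A alone and 258 in MDA-MB-231 alone, was not shown to differ from the 9 and 26 of shared regions (Fisher's exact test, p = 0.365). For H3K27me3 regions found only in MDA-MB-231 the split, 47 and 6, did differ (Fisher's exact test, p = 2.03e-09). Copy number and read depth at these regions were not tested, and they stay open.

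H3K9me2 and H3K27me3 regions coincided in both lines, with the higher fold in MDA-MB-231, although the difference of the lines was not tested. Part of the overlap was not specific to a line, since MDA-MB-231 H3K9me2 regions overlapped H3K27me3 of MCF-10A at 13.96%, with a fold of 2.76 over local moves, and MCF-10A H3K27me3 regions overlapped H3K9me2 of MDA-MB-231 at a fold of 3.12 and that of MCF-10A at 2.49. Peak density at the scale of the local moves is argued against as the whole cause by the fold of 3.52 in MDA-MB-231 (permutation p = 0.002). Each region was moved on its own by at least 50 kb, which breaks up narrower clusters such as the block on chromosome 19. Dense clusters below that size therefore stay open as a cause, and the permutation p treats clustered regions as independent. Regions with peaks of both marks in both lines are argued against as the whole cause, since the fold was 3.46 (permutation p = 0.002) over the 2605 regions left without them. Local gains of DNA in MDA-MB-231, which may raise peaks of both weak marks together, were not tested and stay open, as does a difference of the lines in the marks themselves.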

How the results depend on the processing

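Scaling within chromosomes, shifts within chromosomes, local moves, the pair H3K9me2 and H3K27me3, the bins compared between marks, the H3K27me3 classes, the chromosome shares and leaving out libraries for peak numbers and Jaccard indices were chosen only after results were seen. The cause was not tested for any change given here, except that a left-out library eases the rule for a region (1 replicate in place of both). In the bin test it leaves 1 library in a line, and limma assumes that a lone library varies like the others. Bin calls did not always fall there: those of H3K27me3 and H3K9me2 higher in MCF-10A rose without either MDA-MB-231 library. Of the alternatives for the values that answer a comparison, 200 were kept, 60 moved, 3 lost the threshold and 1 reversed. Tests were kept if their direction and side of the threshold stayed. Ratios of peak numbers and differences of Jaccard indices were kept if they stayed within the spread. Counts of regions and bins were kept if their ratio to the main count stayed within a fixed limit, so a kept count could still differ. Of 210 alternatives for named bins that could be tested, 207 kept the call, 3 lost it and none reversed. The log2 ratio of the lost calls was 1.42 for H3K27me3 at chromosome 6 from 41000001 unscaled, and with a score of at least 100 it was −6.76 for H3K27me3 at chromosome 8 from 11000001 and 5.89 for H3K9me2 at chromosome 20 from 59000001, both farther from 0 than with all peaks. The H3K9me2 bins at chromosome 6 from 136000001, chromosome 12 from 78000001 and chromosome 2 from 50000001 were covered in too few libraries to be tested with a score of at least 100 or equal list lengths. The depth of the libraries is unknown, so what it limits could not be measured. Promoters, gene lists, promoters with both H3K4me3 and H3K27me3 and the genomic distribution were not run, with all their alternatives, for lack of an hg19 annotation.

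Region counts are given in the order only in MCF-10A, only in MDA-MB-231, in all 4. Counting either replicate gave 2192 and 2274 for H3K4me3, 33397, 24028 and 8861 for H3K27me3, and 10462, 5100 and 2765 for H3K9me2. A score of at least 100 gave 2817, 203 and 131 for H3K27me3 and 985, 223 and 131 for H3K9me2. Equal list lengths gave 2815 MCF-10A regions and 470 in all 4 for H3K27me3, and 2043 MCF-10A regions for H3K9me2. Requiring 50% of a region covered gave 193 H3K27me3 regions in all 4. With each library left out in turn, H3K4me3 ranged from 1257 to 2121 and from 1165 to 1950. H3K27me3 ranged from 7793 to 21695, from 2324 to 21119 and from 1463 to 3706, and H3K9me2 from 4653 to 8150 and from 1815 to 3895.

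Bins are given as higher in MDA-MB-231, then higher in MCF-10A. Bins of 250 kb gave 706 and 626 for H3K4me3, 634 and 1782 for H3K27me3, and 601 and 2359 for H3K9me2, with more bins tested. Unscaled coverage gave 259 H3K4me3 bins higher in MCF-10A and 57 H3K27me3 bins higher in MDA-MB-231. A score of at least 100 gave 75 and 523 for H3K27me3 and 101 and 556 for H3K9me2, and equal list lengths gave 459 H3K27me3 bins higher in MCF-10A. With each library left out, H3K4me3 ranged from 44 to 68 and from 67 to 112, H3K27me3 from 104 to 296 for MDA-MB-231, and H3K9me2 from 161 to 230 for MDA-MB-231. Of the called bins, 709, 885 and 1112 for H3K4me3, H3K27me3 and H3K9me2 kept their direction with scaling within chromosomes, and 0, 5 and 12 turned.

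The labels share replicate numbers between the lines but do not say that these pair the samples. Deviations of same-numbered libraries correlated across bins at r = 0.0895, 0.0211 and −0.0135 for H3K4me3, H3K27me3 and H3K9me2. These low values were not tested and cannot tell whether same-numbered libraries were prepared together. With the replicate number as a block, 386 and 376, 302 and 827, and 248 and 960 bins were called for the 3 marks.

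Against local moves the fold of H3K4me3 with H3K27me3 was 1.06 in MCF-10A (permutation p = 0.308), no longer past the threshold, and 0.654 in MDA-MB-231, where it reversed. Against shifts along the genome the MDA-MB-231 fold, 1.44 with both replicates, ranged from 0.874 to 1.05 with 1 replicate left out, and against local moves the folds of single replicates were 0.386 to 0.609 in MDA-MB-231 and 0.688 to 1.07 in MCF-10A, on both sides of 1. A score of at least 100 gave 0.669 for H3K4me3 with H3K9me2 in MDA-MB-231 (permutation p = 0.394) and an odds ratio of 1.85 (Fisher's exact p = 0.45) for MDA-MB-231 H3K27me3 on H3K4me3 regions found only in MDA-MB-231, both past the threshold before. The log2 ratio of H3K27me3 peaks ranged from −1.77 to 0.0763, and that of H3K9me2 peaks was −1.31 with a score of at least 100. With 1 library left out, the within-line Jaccard index exceeded that across lines by 0.109 to 0.123 for H3K4me3, by 0.0232 to 0.212 for H3K27me3 and by 0.231 to 0.314 for H3K9me2. For H3K27me3 it was 0.106 with all libraries, 0.0248 or 0.0232 without MCF-10A replicate 1 or 2, and 0.163 or 0.212 without MDA-MB-231 replicate 1 or 2. The chromosome correlations and the other odds ratios kept direction and threshold in every alternative run.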

Other observations

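The runs, the regions in many lists and the overlaps below were chosen only after the data were seen.

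H3K4me3 regions specific to a line came in runs along the chromosomes. Counting neighbouring regions of the same class with no other H3K4me3 region between them, 14 runs held at least 5 regions, against a mean of 0.026 in 1000 permutations of the classes. The longest run held 15 regions found only in MCF-10A on chromosome X from 114959768 to 115002745, within 43.0 kb, and the longest in the permutations held 6 (permutation p = 0.001, the smallest these can give). Its peaks in MCF-10A replicate 2 stood at a regular spacing, with a median of 2968 bp and a range of 2756 to 3253 bp. The permutations treated regions as independent of each other, which neighbours at a regular spacing may not be. Their p-value therefore cannot tell 15 separate changes from a single change of the whole stretch. The run began in the bin of chromosome X that had the smallest p for H3K4me3, so these results are not separate. Further MCF-10A runs held 12 regions on chromosome 6 from 26196801 to 26274395, 8 on chromosome 5 from 140186595 to 140464754 and 6 on chromosome 7 from 27152530 to 27183548, with no H3K27me3 peak of MDA-MB-231 within them. On chromosome 5 from 1882302 to 2755580 an MCF-10A run held 6 and 23 H3K27me3 peaks in the MDA-MB-231 replicates and 13 and 9 in the MCF-10A replicates. On chromosome 12 from 54121447 to 54403475 these were 6 and 19, and 5 and 6, on chromosome 19 from 51454904 to 51523212 they were 0 and 2, and 0 and 0, and on chromosome X from 56790211 to 56830196, with 7 regions found only in MCF-10A, they were 0 and 0, and 5 and 6. A run of 6 regions found only in MDA-MB-231 lay on chromosome 19 from 20011086 to 20349414.

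H3K27me3 regions were also set against H3K4me3 of each line. Of the 7389 regions found only in MCF-10A, 5.72% overlapped H3K4me3 of MDA-MB-231 and 3.03% that of MCF-10A, but the 1174 regions in all 4 libraries leaned the same way, at 4.34% and 2.90%, and the splits between the lines were not shown to differ (59 and 258 in MCF-10A or MDA-MB-231 alone against 9 and 26, Fisher's exact test, p = 0.365). Of the 1982 found only in MDA-MB-231, 3.88% overlapped H3K4me3 of MCF-10A and 1.82% that of MDA-MB-231, a split of 47 and 6 that differed from the shared regions (Fisher's exact test, p = 2.03e-09, adjusted p = 8.1e-09 over 4 tests). These are the lists already compared from the side of H3K4me3, so the counts are not independent of that comparison.

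Of 92795 regions merged over all 12 lists, 112 had peaks in at least 8 lists and none in all 12. Peaks in 11 lists lay on chromosome 1 from 148925700 to 148933651 and from 161409453 to 161442312, and on chromosome 9 from 66454629 to 66459108.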
